A study of Mus musculus with 19 samples.

How the data were processed

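RNA was measured by strand-preserving sequencing libraries (NEBNext Ultra Directional kit, 1 µg of total RNA per the labels) from prostates of mice of the strain C57BL/6N x BALB/C. The labels give 4 groups in 19 libraries: normal prostate with Otud6a (n=5), normal prostate without Otud6a (n=5), Hi-Myc tumours with Otud6a (n=4) and Hi-Myc tumours without Otud6a (n=5). The groups were taken from the sample descriptions and, for Hi-Myc tumours without Otud6a, from the genotype label. No Hi-Myc tumour with Otud6a is numbered 3.

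The authors deposited 1 table of FPKM for 55564 features (53801 Ensembl genes and 1763 unannotated features), with gene length, position and strand. Per the submitters' processing notes, reads were aligned with Bowtie 0.12.2 to mm8. The table itself carries GRCm38 positions: of the 53706 Ensembl genes that are also in GENCODE mouse release 21, 52142 (97.1% of these) have the same coordinates, and 134 features lie on patch scaffolds. Positions are therefore given as GRCm38. The counting tool and the way the library size was set are not given in the sources used here. Multiplied by gene length, the values of each library were whole multiples of 1 constant (100% of values, within 0.001 reads), so reads per gene and library were recovered. The library size implied by the FPKM was 0.660 to 1.38 times the sum of recovered reads. Recovered reads ranged from 10928878 to 17177358 per library (median 15656984). The 95% intervals of shares of reads lay within ±0.0288 percentage points of the share and cover counting error only, and a floor of 3 reads was used for genes listed at 0. Pairs of libraries of a group were compared for duplicates, and none was found.

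Gene tests used limma 3.58.1 in R 4.3.3 on log2(FPKM+1), with 1 fit over all 19 libraries, 1 coefficient per group, and moderated variances with a trend and robust estimation. Genes with at least 1 FPKM in at least 4 libraries were tested (15237 features, 722 of them unannotated). The 5 comparisons were Hi-Myc tumour against normal with Otud6a and without it, loss of Otud6a in tumours and in normal prostate, and the interaction. P-values were adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. The named genes are, for each comparison, Myc, 8 genes that rose and 8 that fell, and members with the smallest p of lists the list test called. The 8 either way had the largest fold changes among passing genes whose compared groups did not overlap. They also needed a mean of at least 1 FPKM in the libraries compared and a symbol that is not provisional. Where too few such genes existed, the rest were taken by smallest p. For normal prostate the 5 smallest p-values were taken instead, and for the interaction the 8 smallest. Some genes chosen by this rule are not reported here, and they stay in all tests and lists. Genes were also named where they are known markers of tissue or lie beside Otud6a. Families of near-identical genes (globins, beta-defensins, Sbp and Sbpl, C1rb and C1s2) can share reads, and ribosomal protein genes have many pseudogenes.

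The 30 gene lists, covering MYC targets, growth, metabolism, prostate, other tissues, immune cells and stress, were written before the data were examined, as were the groups, the 5 comparisons and the filter. Of 552 names 547 were matched, 4 of them as a second name of a gene already in the list. Lists with at least 5 tested members were tested (28 lists), and those for B and plasma cells and neuroendocrine cells had fewer. The list test was camera with a preset correlation of 0.01. The estimated correlation and fry were run beside it, and members were also adjusted over the list alone. Camera compares a list with the other genes, and fry tests whether its members move on balance one way. Scores per library, shares of reads, principal components and figures were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

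Each gene and list count was set against 100 splits of the same samples into groups of the same sizes, the real one included. The correlations between comparisons that share a group were set against 100 simulations in which only the shared group links them, against permuted labels, and against splits in which no library is shared. Features within 1.0 Mb of Otud6a were tested for reads found in libraries of 1 genotype by an exact two-sided permutation test with genotype permuted within tissue. This locus test was added after the data were seen.

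Other settings fixed before the data were examined were quantile normalization, no filter on low values, a pseudocount of 0.1, a block for replicate number, only the 2 groups compared, a fold change of at least 1 on the log2 scale, the estimated correlation, and leaving out each library in turn. Settings chosen after the data were seen were scaling to each library's sum of reads, limma-voom on recovered reads, and leaving out libraries with at least 5% of reads from the seminal vesicle list, at least 1% from the skeletal muscle list or at least 20% mitochondrial reads, or normal libraries whose median correlation with their group was under 0.9. The pipeline was tested on simulated data with the same libraries and groups, in which genes were changed 2-fold, 4-fold and 8-fold. It recovered 11.9% to 17.9%, 59.1% to 64.1% and 68.8% to 81.8% of them in the 4 comparisons of groups, and 1.52%, 25.4% and 60.0% in the interaction. False calls were 5.94% to 11.2% of calls in the group comparisons, above the nominal 5% share, and 0 in the interaction. The voom alternative was not part of that test. No library was left out of the main results.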

Results

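Whole-transcriptome RNA sequencing of mouse prostate was examined in 19 libraries from 4 groups that cross the Hi-Myc transgene with loss of Otud6a. The groups were normal prostate with Otud6a (Otud6a+/y, n=5), normal prostate without it (Otud6a-/y, n=5), Hi-Myc tumours with Otud6a (n=4, replicates 1, 2, 4 and 5) and Hi-Myc tumours without it (n=5). Libraries held 10928878 to 17177358 reads assigned to genes (median 15656984). Expression was the authors' FPKM, and 15237 of 55564 features, 722 of them unannotated, passed the expression filter. Group values are mean FPKM ± SD. Fold changes are differences of log2(FPKM+1), given with their standard errors in brackets, and understate the change of genes with low values. P-values below, other than those of the list test, measure spread between these samples. Adjusted p-values come from limma unless another test is named. The list test sets the genes of a list against the other genes, with a preset correlation of 0.01 between genes. Its p-values thus treat the genes of a list as nearly independent and do not measure spread between samples.

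Otud6a itself (chromosome X, 100429013 to 100429885, GRCm38) could not check the genotype labels. It had 1 read in normal Otud6a+/y replicate 1 (0.0678 FPKM) and 0 reads in the other 18 libraries, and a floor of 3 reads corresponded to 0.166 to 0.365 FPKM over the 19 libraries. Its neighbours could. An unannotated feature 16.1 kb beyond it on the same strand (chromosome X, 100445952 to 100456769) had reads in 9 of 9 Otud6a+/y libraries (570 reads in sum) and in 1 of 10 Otud6a-/y libraries (1 read, in tumour replicate 3). Dgat2l6, which encodes an acyltransferase of lipid synthesis and lies 95.0 kb from Otud6a (chromosome X, 100524838 to 100546144), had reads in 8 of 9 Otud6a+/y libraries (197 reads) and in 0 of 10 Otud6a-/y libraries, the exception being normal Otud6a+/y replicate 4. Each gave an exact permutation p of 0.000189 with genotype permuted within tissue (adjusted p = 0.00312 over the 33 features with reads within 1.0 Mb). Igbp1, between them, had reads in every library. Across all 55564 features these 2 were the only ones found in at least 8 of the 9 Otud6a+/y and at most 1 of the 10 Otud6a-/y libraries, and 0 features showed the opposite pattern. These locus tests were chosen after the data were seen.

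Genes known from organs other than prostate took large shares of some libraries. The seminal vesicle list took 23.8% of reads in normal Otud6a+/y replicate 1, 34.9% in normal Otud6a-/y replicate 4, and 26.1% and 25.3% in Otud6a+/y tumour replicates 4 and 5. Svs2, a seminal vesicle secretory protein, alone took 14.3%, 25.5%, 18.4% and 16.2% there. Otud6a+/y tumour replicates 1 and 2 instead carried skeletal muscle transcripts (5.70% and 6.56% of reads, against at most 0.0958% in the other 17 libraries). Those 2 libraries also carried gland transcripts that were near 0 in all others: Prol1 (proline rich, lacrimal 1) took 6.65% and 5.66% of reads, Smr2 stood at 998 and 914 FPKM, Pip, the prolactin-induced protein, at 751 and 469 FPKM, and Dcpp1 at 4296 and 778 FPKM. Thus each of the 4 Otud6a+/y tumour libraries was rich in transcripts of 1 of these tissues, and none of the 5 Otud6a-/y tumour libraries was. Counting error was small beside these shares (95% intervals within ±0.0288 percentage points), and intervals and floors here cover counting error alone.

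Hoxb13, a homeobox regulator of prostate, stood at 3.19 ± 1.37 FPKM in Otud6a+/y tumours and 98.7 ± 64.4 FPKM in Otud6a-/y tumours, beside 109 ± 44.4 and 88.5 ± 64.5 FPKM in the normal groups. The first component of variation held 34.1% and the second 21.4%. Otud6a+/y tumours formed 2 pairs: the correlation was 0.964 between replicates 1 and 2, 0.969 between replicates 4 and 5, and 0.747 to 0.800 across the pairs. Mitochondrial reads were highest in Otud6a-/y tumour replicates 5 (37.1%) and 1 (25.4%) and in Otud6a+/y tumour replicate 2 (24.2%).

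**Figure D1:**
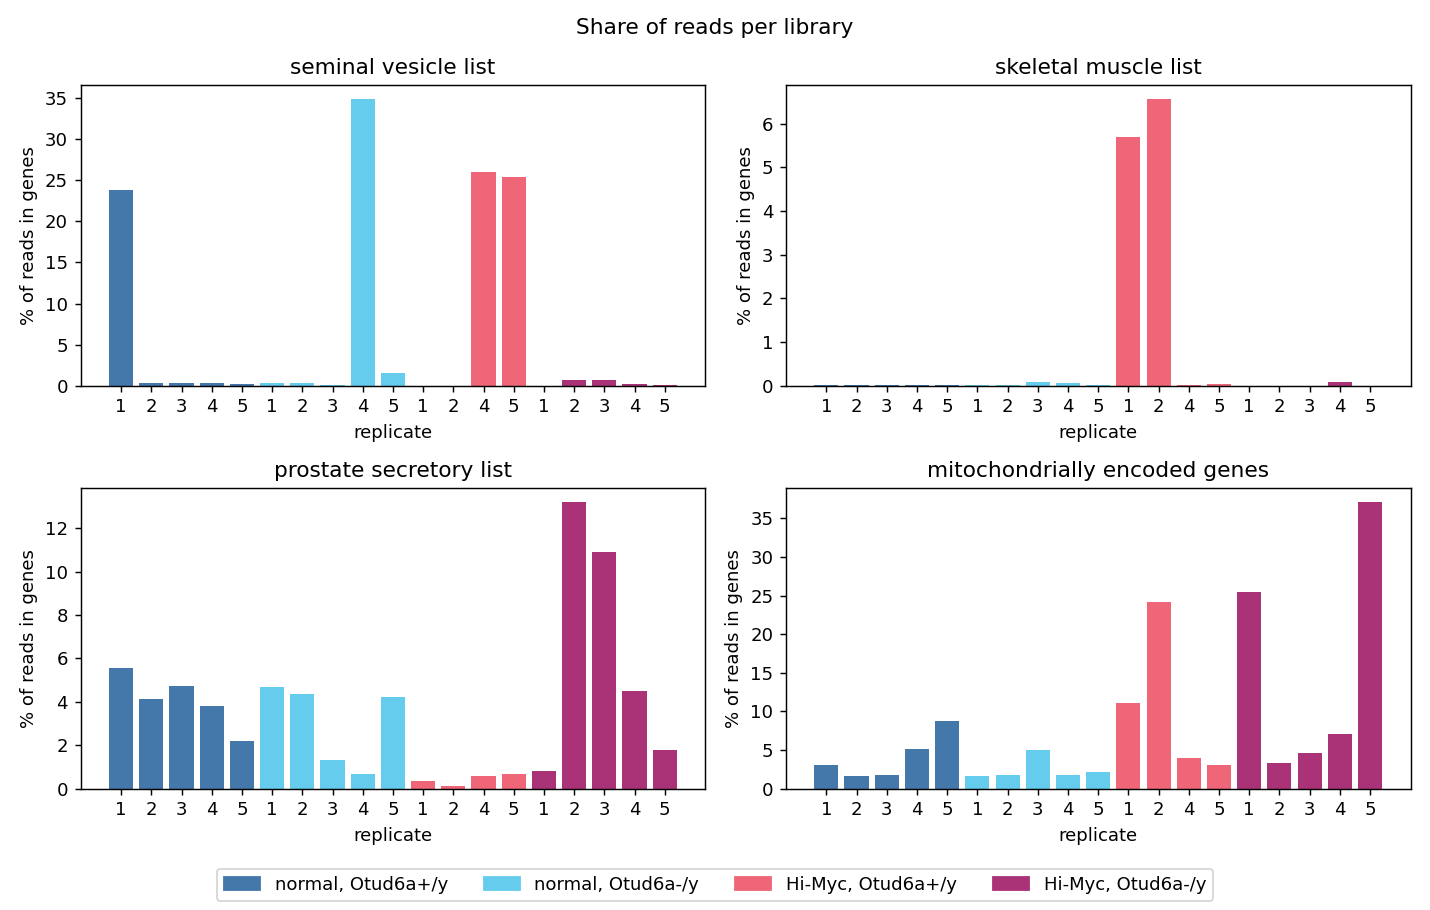
Percent of reads from 4 gene lists (seminal vesicle, skeletal muscle, prostate secretory, mitochondrially encoded) in each of the 19 libraries, by group. Seminal vesicle transcripts reached 34.9% and skeletal muscle transcripts 6.56%.

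**Figure D2:**
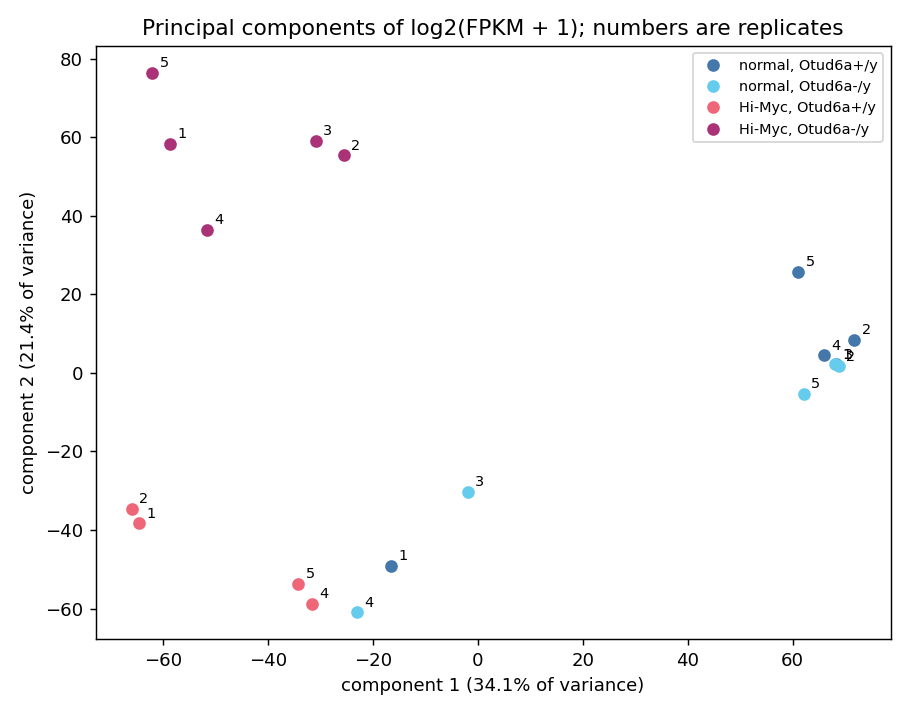
Principal components of log2(FPKM+1) for the 19 libraries, coloured by group, with components 1 (34.1%) and 2 (21.4%) on the axes. Normal Otud6a+/y replicate 1 and normal Otud6a-/y replicates 3 and 4 sit apart from the other 7 normal libraries.

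Between Hi-Myc tumours and normal prostate with Otud6a present, 1115 genes rose and 1237 fell, of 15237 tested. All 4 tumours were rich in transcripts of another organ, and of the normal libraries here only replicate 1 was. These counts and the genes below therefore cannot be credited to Hi-Myc alone. Among genes chosen for their large falls, probasin (Pbsn) fell by log2 9.61 (SE 1.16, adjusted p = 0.0011, from 13752 ± 7808 to 43.4 ± 75.2 FPKM), and renin (Ren1, log2 -9.50, SE 1.25), the prostate transglutaminase Tgm4 (-9.10, SE 1.24), C1rb (-8.02), Glb1l3 (-7.69), C1s2 (-7.52), Gsdma (-6.98) and Pnliprp1 (-6.57) fell with it. Lactotransferrin (Ltf) rose by 6.87 (SE 1.09, adjusted p = 0.004), Ly6d by 5.87, the fast troponin Tnni2 by 6.48, myoglobin (Mb) by 6.22, Atp2a1 by 5.93, Myl1 by 5.88 and Eef1a2 by 5.77. Wfdc12, a secreted protease inhibitor, was listed at 0 in all 5 normal libraries and at 171 ± 240 FPKM in tumours (adjusted p = 0.00192). These genes were chosen among those in which the 4 tumour and 5 normal libraries do not overlap, so the lack of overlap is no added support. Of the 20 genes of the prostate secretory list 2 rose, 6 fell and 12 did not pass (3 and 7 adjusted over the list alone; list test adjusted p = 0.0569, adjusted p = 0.668 with an estimated correlation).

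Mouse Myc (chromosome 15, 61985391 to 61990374) fell in the same comparison, by log2 1.01 (SE 0.28, adjusted p = 0.0272, from 25.7 ± 4.88 to 12.3 ± 2.80 FPKM). The transgene encodes human MYC, so these reads need not report it. Of 29 measured MYC targets of the nucleolus and ribosome assembly 0 rose, 4 fell (Nop58 -0.69, Gar1 -0.96, Rcl1 -0.73, Nip7 -0.67) and 25 did not pass (4 adjusted over the list alone; list test adjusted p = 0.00459, adjusted p = 0.668 with an estimated correlation). Of 34 metabolic and translation targets 6 fell, among them the amino acid transporter Slc7a5 (-2.48), Mthfd2 of the folate cycle (-1.42) and the helicase Eif4a1 (-0.78), and 28 did not pass (6 adjusted over the list alone; 0.0112 and 0.668). Ribosomal protein genes fell in 4 of 30 cases, Rpl10a (-0.96) among them, with 0 adjusted over the list alone (3.31e-06 and 0.668). Cell cycle genes gave 0 of 24 either way (adjusted p = 0.0681).

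Genes of endoplasmic reticulum stress and folding fell in 9 of 18 cases, with 9 not passing and 15 passing adjusted over the list alone. The list test gave an adjusted p of 1.95e-06, and 0.668 with an estimated correlation. The genes that fell included the disulfide isomerase Pdia6 (-2.71, adjusted p = 0.00526), Creld2 (-2.36), Trib3 (-1.97) and Manf (-1.55). Interferon response genes rose in 7 of 20 cases (10 adjusted over the list alone; 1.33e-05 and 0.668): Oas1a by 1.96 (SE 0.43), Ifit1 by 1.92, Rtp4 by 1.89 and Usp18 by 1.54. Macrophage genes rose in 2 of 15, lysozyme Lyz2 by 3.15 (SE 0.69, adjusted p = 0.0118) and complement C1qc by 1.65 (2 adjusted over the list alone; 0.000178 and 0.668). Endothelial genes rose in 3 of 14, Pecam1 by 1.38, Tek by 1.03 and Flt1 by 0.88 (7 adjusted over the list alone; 0.00081 and 0.668). Among 20 fibroblast and matrix genes Vim rose by 2.08 and 19 did not pass (0 adjusted over the list alone; 0.00191 and 0.668).

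Skeletal muscle genes rose in 11 of 12 cases, among them Tnnt3 by 6.79 and creatine kinase Ckm by 5.79 (12 adjusted over the list alone; list test adjusted p = 3.31e-06, adjusted p = 0.668 with an estimated correlation). Nuclear genes of oxidative phosphorylation rose in 3 of 23, Sdha by 1.40 (adjusted p = 0.0302), Ndufa9 by 1.40 and Ndufs1 by 1.32 (3 adjusted over the list alone; 2.17e-05 and 0.668). Globin and other red blood cell genes rose in 4 of 5, such as Hbb-bs by 2.32 and Hba-a1 by 2.26 (4 adjusted over the list alone; 0.0114 and 0.668). The 13 mitochondrially encoded genes gave 0 either way with a list test adjusted p of 0.00516 (0.668 with an estimated correlation). The count of called genes rested on single libraries: it was 298 without tumour replicate 1, 807 without tumour replicate 2, and 3859, 919, 1240, 951 and 1080 without normal replicates 1 to 5 in turn. It was 18 with tumour replicates 1 and 2 both left out, where 2 tumours remain, and the median of the oxidative phosphorylation list then turned from 0.87 to -0.19, and that of the mitochondrially encoded list fell from 1.46 to 0.02. The skeletal muscle median fell from 5.23 to 0.59 and that of red blood cells from 2.13 to 1.16. Other medians kept their sign with 0 genes called: stress and folding -1.396 and -1.396, ribosomal protein -0.658 and -0.657, nucleolar -0.327 and -0.554, interferon 1.071 and 0.944, fibroblast 1.201 and 1.089.

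Between the tumour genotypes, 1470 genes were higher and 1474 lower in Otud6a-/y than in Otud6a+/y tumours. Tissue content differed with genotype here, so these counts cannot be credited to loss of Otud6a alone. Rises and falls below are differences between these 2 groups. Crabp1, a retinoic acid binding protein, rose by log2 6.41 (SE 0.76, adjusted p = 3.75e-05, from 2.45 ± 3.78 to 273 ± 224 FPKM), the beta-defensin Defb29 by 5.80 (SE 0.39, adjusted p = 1.2e-07, from 1.15 ± 0.532 to 148 ± 109 FPKM), Defb50 by 5.39, the phosphatidylserine receptor Havcr1 by 4.88 (SE 0.38, adjusted p = 6.94e-07), the anion exchanger Slc26a4 by 4.67, Hoxb13 by 4.38 (SE 0.75, adjusted p = 0.000968), and Scgb2b27 by 4.22. Crisp1, a secretory protein known from the epididymis, fell by 9.71 (SE 2.34, adjusted p = 0.00847), and so did Odam (-6.84), Cdo1 of cysteine breakdown (-5.91, adjusted p = 0.047), the epithelial transcription factor Elf5 (-5.72), Mybpc1 (-5.54), Casq1 (-4.84), Ltf (-4.82) and the small heat shock protein Hspb6 (-4.50). These genes were chosen among those in which the 2 groups of tumours do not overlap, so the lack of overlap is no added support. Several of those that fell were also high where tissue of another organ was. Cdo1, Elf5 and Odam were set apart in the 2 normal libraries rich in seminal vesicle transcripts, Otud6a+/y replicate 1 (1825, 99.3 and 24.7 FPKM, nearest 5.10, 7.67 and 1.09) and Otud6a-/y replicate 4 (3658, 144 and 31.7 FPKM, nearest 90.9, 11.5 and 1.83). Mybpc1 and Casq1, known from skeletal muscle, were highest in the 2 muscle-rich tumours (392 and 570 FPKM, 291 and 353 FPKM). Cdkn2a, which encodes cell cycle inhibitors, rose by 2.02 (SE 0.26, adjusted p = 0.000103) and was at or above 3.29 FPKM in all 5 Otud6a-/y tumours and at or below 1.23 FPKM in all 4 with Otud6a.

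Cell cycle genes rose in 15 of 24 cases in Otud6a-/y against Otud6a+/y tumours and 9 did not pass (16 adjusted over the list alone; list test adjusted p = 5.44e-10, adjusted p = 0.521 with an estimated correlation): the proliferation marker Mki67 by 1.66 (SE 0.29, adjusted p = 0.00103, from 0.83 ± 0.447 to 5.27 ± 3.55 FPKM), the cyclin Ccnb2 by 1.54, topoisomerase Top2a by 1.46 and the spindle checkpoint kinase Bub1b by 1.41. Nucleolar MYC targets rose in 18 of 29 (20 adjusted over the list alone; 5.44e-10 and 0.521), among them Ppan by 2.02, nucleophosmin (Npm1) by 1.59 (SE 0.29, from 66.3 ± 9.05 to 206 ± 51.8 FPKM), Gar1 by 1.30 and Nop58 by 0.98. Metabolic MYC targets rose in 9 of 34, fell in 1 and did not pass in 24 (14 and 1 adjusted over the list alone; 0.000313 and 0.588), with Ctps, a nucleotide synthesis enzyme, up by 1.26, Cdk4 by 1.14 (adjusted p = 0.000222), Eif4a1 by 1.10 and Nme1 by 1.09. Ribosomal protein genes rose in 28 of 30 (29 adjusted over the list alone; 4.44e-16 and 0.521), such as Rpl3 by 1.67, Rpl10a by 1.64, Rps19 by 1.62 and Rpl18 by 1.25. Mouse Myc differed by -0.44 (SE 0.28, adjusted p = 0.288). Otud6a-/y tumour replicate 1, with 25.4% mitochondrial reads, stood apart in its group for Mki67 (11.5 FPKM, nearest 4.20) and Bub1b (4.73, nearest 2.25). The mean log2(FPKM+1) of the cell cycle list was 2.87 in it and 1.757 to 1.956 in the other Otud6a-/y tumours. All of these lay above the Otud6a+/y tumours (1.045 to 1.336). Each Otud6a+/y library in this comparison was rich in transcripts of another organ.

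Interferon response genes rose in 12 of 20 cases between the same tumours (14 adjusted over the list alone; list test adjusted p = 1.78e-08, adjusted p = 0.521 with an estimated correlation), with the nucleic acid sensor Zbp1 up by 2.29, Oas1a by 2.04, tetherin (Bst2) by 1.87 and Ifit1 by 1.73. Macrophage genes rose in 11 of 15 (12 adjusted over the list alone; 7.56e-06 and 0.569), among them C1qb by 2.04, Aif1 by 1.91, C1qc by 1.87 and Laptm5 by 1.42. The macrophage list held 0.0348% to 0.339% of reads in Otud6a-/y tumours and 0.0191% to 0.0417% in Otud6a+/y tumours. Otud6a-/y replicate 2 (0.0348%) lay within that range, and the highest shares, 0.339% and 0.186%, were those of Otud6a-/y replicates 1 and 5, which had 25.4% and 37.1% mitochondrial reads. Of 7 T and NK cell genes Lck, a T cell kinase, rose by 1.37 and 6 did not pass (1 adjusted over the list alone; 0.0356 and 0.588). Of 7 neutrophil and inflammation genes 1 rose and 6 did not pass (1 adjusted over the list alone; 0.0786 and 0.678). Of 20 fibroblast and matrix genes the collagen Col6a3 rose by 3.53 and the protease inhibitor Timp1 by 2.75 (2 adjusted over the list alone; 0.0133 and 0.678), and the list's median turned from 0.78 to -0.21 without the 3 libraries richest in mitochondrial reads.

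Prostate secretory genes rose in 9 of 20 cases (11 adjusted over the list alone; list test adjusted p = 1.7e-05, adjusted p = 0.509 with an estimated correlation), among them Bex1 by 3.22 (adjusted p = 1.51e-05) and Apof by 2.44. That list held 13.2%, 10.9%, 4.50%, 1.78% and 0.824% of reads in Otud6a-/y tumour replicates 2, 3, 4, 5 and 1, and 0.122% to 0.702% in Otud6a+/y tumours. Smooth muscle genes fell in 6 of 16 (8 adjusted over the list alone; 7.56e-06 and 0.564): Tpm2 (-4.47), desmin (Des, -4.12) and Synm (-3.96). Skeletal muscle genes fell in 5 of 12, such as Acta1 (-6.68) and Ckm (-6.03) (12 adjusted over the list alone; 3.75e-05 and 0.588). Oxidative phosphorylation genes fell in 8 of 23, among them Sdha (-1.76), Ndufa4 (-1.36) and Sdhb (-1.26) (11 adjusted over the list alone; 9.87e-06 and 0.588). Endothelial genes fell in 2 of 14, Flt1 (-1.10) and Ptprb (-1.01) (3 adjusted over the list alone; 0.0231 and 0.678), and red blood cell genes in 3 of 5, such as Hbb-bs (-2.76) (4 adjusted over the list alone; 0.0234 and 0.569). The count of called genes, 2944, was 1855 without Otud6a+/y tumour replicate 1. It was 3601 (1395 up, 2206 down, 2138 shared) without the libraries rich in seminal vesicle transcripts and 1666 (1046 up, 620 down) without those rich in mitochondrial reads. Without Otud6a+/y tumour replicates 1 and 2 it was 1849, with cell cycle genes higher in 12, nucleolar targets in 13, ribosomal protein genes in 15 and macrophage genes in 3 cases, and oxidative phosphorylation genes lower in 0, their median turning from -1.02 to 0.11. With 2 Otud6a+/y tumours left, the other medians did not shrink much: cell cycle 0.964 to 1.086, nucleolar 0.696 to 0.907, ribosomal protein 1.197 to 1.161 and macrophage 1.646 to 1.845. Smooth muscle genes were then lower in 13 of 16 and seminal vesicle genes in 6 of 9 (median -9.01), and the median of the mitochondrially encoded list turned from -0.14 to 1.37.

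Whether loss of Otud6a changes normal prostate was answered by 0 genes: limma called none of 15237 (smallest adjusted p = 1), with 129 genes at an unadjusted p under 0.05, and voom on recovered reads also called 0. Libraries of the 2 genotypes did not overlap in 36 genes, 0.236% of those tested, where chance gives 0.794%. The 5 genes with the smallest p were Gm27817 (log2 -1.45), the unannotated feature beside Otud6a (listed at 0 in all 5 Otud6a-/y libraries and at 1.63 ± 1.22 FPKM with Otud6a), Gm8524 (0.78), AC115304.2 (-0.85) and Gm17828 (-0.89), each with adjusted p = 1. Mouse Myc differed by -0.40 (SE 0.27), Mki67 stood at 0.316 ± 0.136 and 0.505 ± 0.392 FPKM, and Hbb-bs, a globin, differed by 1.62 (SE 0.54). In simulated data of these group sizes 13.4% of genes planted with a 2-fold change and 81.8% of those planted with an 8-fold change were recovered.

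The list test nevertheless called 13 lists in normal prostate, with 0 members past the threshold in any of them. Higher without Otud6a were red blood cells (adjusted p = 4.58e-07, adjusted p = 0.14 with an estimated correlation, 4 of 5 members adjusted over the list alone), smooth muscle (1.31e-05 and 0.707), cell cycle (0.000194 and 0.707), fibroblast and matrix (0.000758), endothelium (0.000758), oxidative phosphorylation (0.0157), macrophage (0.0157), fatty acid and cholesterol synthesis (0.0168) and adipocyte genes (0.0184). Lower were mitochondrially encoded (0.00489), prostate secretory (0.0318), nucleolar MYC target (0.0393) and MYC network genes (0.0464). With an estimated correlation 0 lists were called in this and in each of the other 4 comparisons, and 12 of 100 splits of the samples, the real one included, called as many lists here and 26 to 35 of 100 in the others. Without Otud6a-/y replicate 4 the count was 7, without Otud6a+/y replicate 4 it was 8, and without the 3 normal libraries that sit apart it was 3. In that last setting the medians of the macrophage (-0.08), adipocyte (-0.17), endothelial (-0.0008054) and secretory lists (0.05) turned sign, and the list test of the MYC network turned direction.

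How Hi-Myc tumours differ from normal prostate when Otud6a is absent was answered by 1635 genes that rose and 1612 that fell. Ren1 fell by log2 10.03 (SE 1.17, adjusted p = 1.95e-05), and so did Tgm4 (-9.19), Pbsn (-8.87, SE 1.09, adjusted p = 3.25e-05), Glb1l3 (-8.07), C1rb (-7.22), C1s2 (-6.64), Pnliprp1 (-6.61) and Spink8 (-6.16). Among genes chosen for their large rises were spermine binding protein (Sbp) by 11.35 (SE 2.38, adjusted p = 0.00299, from 12.003 ± 25.0 to 24273 ± 23841 FPKM), its neighbour Sbpl by 10.01, Wfdc12 by 7.64, the protease inhibitor Spink5 by 7.02 and Defb29 by 6.82 (adjusted p = 2.93e-09). Crabp1 rose by 7.62, the stress regulator Nupr1 by 5.87 and Fam25c by 5.84. These 16 genes were chosen among those whose groups do not overlap, so the lack of overlap is no added support. Several that rose were also high in normal Otud6a+/y replicate 1, a normal library outside this comparison. There Sbp stood at 22118 FPKM (nearest in its group 14.5), Sbpl at 7990, Spink5 at 66.3, Nupr1 at 62.8, Fam25c at 13.9 and Crabp1 at 11.4 FPKM. Wfdc12 and Defb29 were not set apart there. Fam25c also reached 27.2 FPKM in normal Otud6a-/y replicate 3. A rise of these genes is thus not particular to tumours. Mouse Myc fell by 1.05 (SE 0.27, adjusted p = 0.0104), and normal replicate 3 (8.45 FPKM) lay within the tumour range of 6.95 to 11.3 FPKM.

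Cell cycle genes rose in 16 of 24 cases in this comparison (20 adjusted over the list alone; list test adjusted p = 3.25e-11, adjusted p = 0.47 with an estimated correlation), Mki67 by 1.95 (SE 0.27, adjusted p = 0.000102), Ccnb2 by 1.59, Bub1b by 1.32 and Ccnb1 by 1.13. Nucleolar MYC targets rose in 11 of 29 (12 adjusted over the list alone; 3.59e-06 and 0.544), such as Nop56 by 1.39, fibrillarin (Fbl) by 1.30 and Npm1 by 1.12. Ribosomal protein genes rose in 10 of 30, Rps19 by 1.18 among them (19 adjusted over the list alone; 2.93e-07 and 0.559). Metabolic targets went both ways, 5 up (Ctps by 1.29, Cdk4 by 0.80) and 4 down (Slc7a5 -3.38, Mthfd2 -2.55) of 34, with a list test adjusted p of 0.172. Secretory genes rose in 9 and fell in 4 of 20 (11 and 4 adjusted over the list alone; 0.0182 and 0.544), Bex1 by 4.28.

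Interferon response genes rose in 19 of 20 cases without Otud6a (19 adjusted over the list alone; list test adjusted p = 1.22e-16, adjusted p = 0.47 with an estimated correlation), with Oas1a up by 3.80 (adjusted p = 8.34e-06), Ifit1 by 3.51, Rtp4 by 3.35 and Zbp1 by 3.22. Macrophage genes rose in 15 of 15 (15 adjusted over the list alone; 3.25e-11 and 0.47), such as Lyz2 by 3.54 and Cd68 by 2.55. T and NK cell genes rose in 5 of 7 (6 adjusted over the list alone; 0.00229 and 0.53), among them granzyme Gzmb by 1.83 and Cd8a by 1.07. Neutrophil and inflammation genes rose in 3 of 7 (5 adjusted over the list alone; 0.0232 and 0.559): S100a9 by 1.96 and Csf3r by 1.68 among them. Otud6a-/y tumour replicate 1, with 25.4% mitochondrial reads, stood apart in its group for S100a9 (35.5 FPKM, nearest 7.19), Cd8a (3.54, nearest 1.48), Cxcl1, Ccl2 and Klrd1. Without the libraries rich in mitochondrial reads S100a9 gave 0.60 (adjusted p = 0.165). Of the 12 list calls 9 then remained, the neutrophil, fibroblast and mitochondrially encoded lists being lost. Fibroblast and matrix genes rose in 9 of 20 (10 adjusted over the list alone; 1.77e-05 and 0.559), with Timp1 up by 4.29, Col6a3 by 3.46 and Col3a1 by 2.76. Smooth muscle genes fell in 12 of 16 (15 adjusted over the list alone; 2.3e-07 and 0.47), Synm (-3.17), Des (-2.92) and Lmod1 (-2.76) among them. Endoplasmic reticulum stress and folding genes fell in 14 of 18 (15 adjusted over the list alone), Dnajb9 (-2.90), Herpud1 (-2.82) and Pdia4 (-1.93) among them. Their list test gave an adjusted p of 8.09e-08, and 0.47 with an estimated correlation. Mitochondrially encoded genes rose in 2 of 13, mt-Atp6 by 2.60 and mt-Co1 by 2.24 (13 adjusted over the list alone; 0.00026 and 0.559).

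Whether the Hi-Myc change depends on Otud6a was tested by the interaction, in which 705 genes were higher and 580 lower without Otud6a than the separate changes add up to. This balance turned to 941 higher and 1647 lower without the libraries rich in seminal vesicle transcripts, 618 and 732 without Otud6a+/y tumour replicate 4, 627 and 759 without replicate 5, and 409 and 462 without the 2 muscle-rich libraries. The interaction takes in the tissue content of the Otud6a+/y tumours. The 8 smallest p-values belonged to AC130671.1, a noncoding RNA at chromosome 15, 27459835 to 27463449 (9.99 ± 2.94 FPKM in Otud6a-/y tumours and at most 0.111 on average elsewhere, adjusted p = 2.06e-06), Defb29 (chromosome 2, 152538714 to 152540098, adjusted p = 2.37e-05), the scaffold gene Mpp1 (chromosome X, 75109733 to 75131016, log2 2.27, SE 0.23), the manganese transporter Slc30a10 (3.45, SE 0.36), Havcr1 (chromosome 11, 46735080 to 46779578, 5.03, SE 0.53), an unannotated feature at chromosome 9, 67013054 to 67022588 (2.87, SE 0.31), Tmem156 (1.95) and Tmem54 (2.86, adjusted p = 9.81e-05). Mpp1 went from 4.21 ± 0.966 FPKM in Otud6a+/y tumours to 22.7 ± 3.54 FPKM in Otud6a-/y tumours and Tmem54 from 3.83 ± 1.20 to 27.3 ± 4.96 FPKM. Mouse Myc gave -0.04 (adjusted p = 0.966).

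By list, the interaction passed with a positive term for 17 of 30 ribosomal protein genes (29 adjusted over the list alone; list test adjusted p = 2.66e-14, adjusted p = 0.545 with an estimated correlation), 8 of 29 nucleolar MYC targets (18; 2.56e-09 and 0.527), 6 of 24 cell cycle genes (11; 8.52e-06 and 0.617), 5 of 34 metabolic MYC targets (6; 0.00178 and 0.617), 5 of 20 secretory genes (9; 8.52e-06 and 0.413), 2 of 20 interferon genes (13; 2.68e-06 and 0.617) and 0 of 15 macrophage genes (0; 0.00178 and 0.617). It passed with a negative term for 6 of 16 smooth muscle genes (6; 2.34e-07 and 0.527), 4 of 5 red blood cell genes (4; 0.000924 and 0.527), 2 of 14 endothelial genes (2; 0.00194 and 0.617), 1 of 23 oxidative phosphorylation genes (1; 5.2e-06 and 0.617) and 1 of 12 skeletal muscle genes (2; 5.18e-05 and 0.617). Whether passing or not, the term was positive for all 30 ribosomal protein, 20 interferon and 15 macrophage genes, and for 0 oxidative phosphorylation or skeletal muscle genes. The interaction count of 1285 was 653 without Otud6a+/y tumour replicate 1, 2101, 703, 760 and 808 without normal Otud6a+/y replicates 1, 2, 4 and 5, 854 without normal Otud6a-/y replicate 4, and 760 without Otud6a-/y tumour replicate 3.

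The comparisons share groups, which ties their results together. Genes called in both the Hi-Myc change with Otud6a and the genotype change in tumours moved in opposite directions in 747 cases (508 up then down, 239 down then up) and the same way in 41, where independent lists would give 227 of each. The fold changes correlated at r = -0.47 (rank correlation -0.44) over 15237 genes that are not independent. The shared Otud6a+/y tumours alone gave r = -0.27 (-0.30 to -0.22) in simulated data, and the covariance differed from the simulated one by -0.29. Giving each comparison its own tumours, with none shared, gave a median of -0.41 (-0.44 to 0.01 over 6 splits). These tumours pair by tissue, so most of those splits kept both tissues on each side and do not remove shared tissue content. Permuted labels gave a mean r of -0.34 with a range (-0.69 to 0.08) that holds the observed value. Their covariance of -0.41 to 0.02 also holds the observed -0.39. The genotype change in tumours and the Hi-Myc change without Otud6a shared 1437 genes moving the same way and 1 moving oppositely (independent lists 314 each), with r = 0.62 against a simulated 0.21 (0.19 to 0.26), a covariance difference of 0.428 and a median of 0.51 (0.29 to 0.56) over 10 splits. Permuted labels gave a mean r of 0.26 with a range (-0.15 to 0.67) that holds the observed value. The covariance of 0.50 lay above its permuted range (-0.05 to 0.41). The Hi-Myc changes with and without Otud6a, which share no library, had 653 called genes in the same direction (192 up, 461 down) and 79 in opposite directions (independent lists 251 each).

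Scaling moved the direction of the overall shift. Scaled to each library's sum of reads, the median gene differed by 0.18 between tumour genotypes and by 0.18 in the interaction, where the deposited values gave -0.05 and -0.03. The tumour genotype comparison then gave 2499 genes up and 674 down, the Hi-Myc comparison 736 and 1258 with Otud6a and 2067 and 841 without it, and the interaction 1199 and 282. Quantile normalization gave 1808 up and 1353 down between tumour genotypes.

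**Figure D3:**
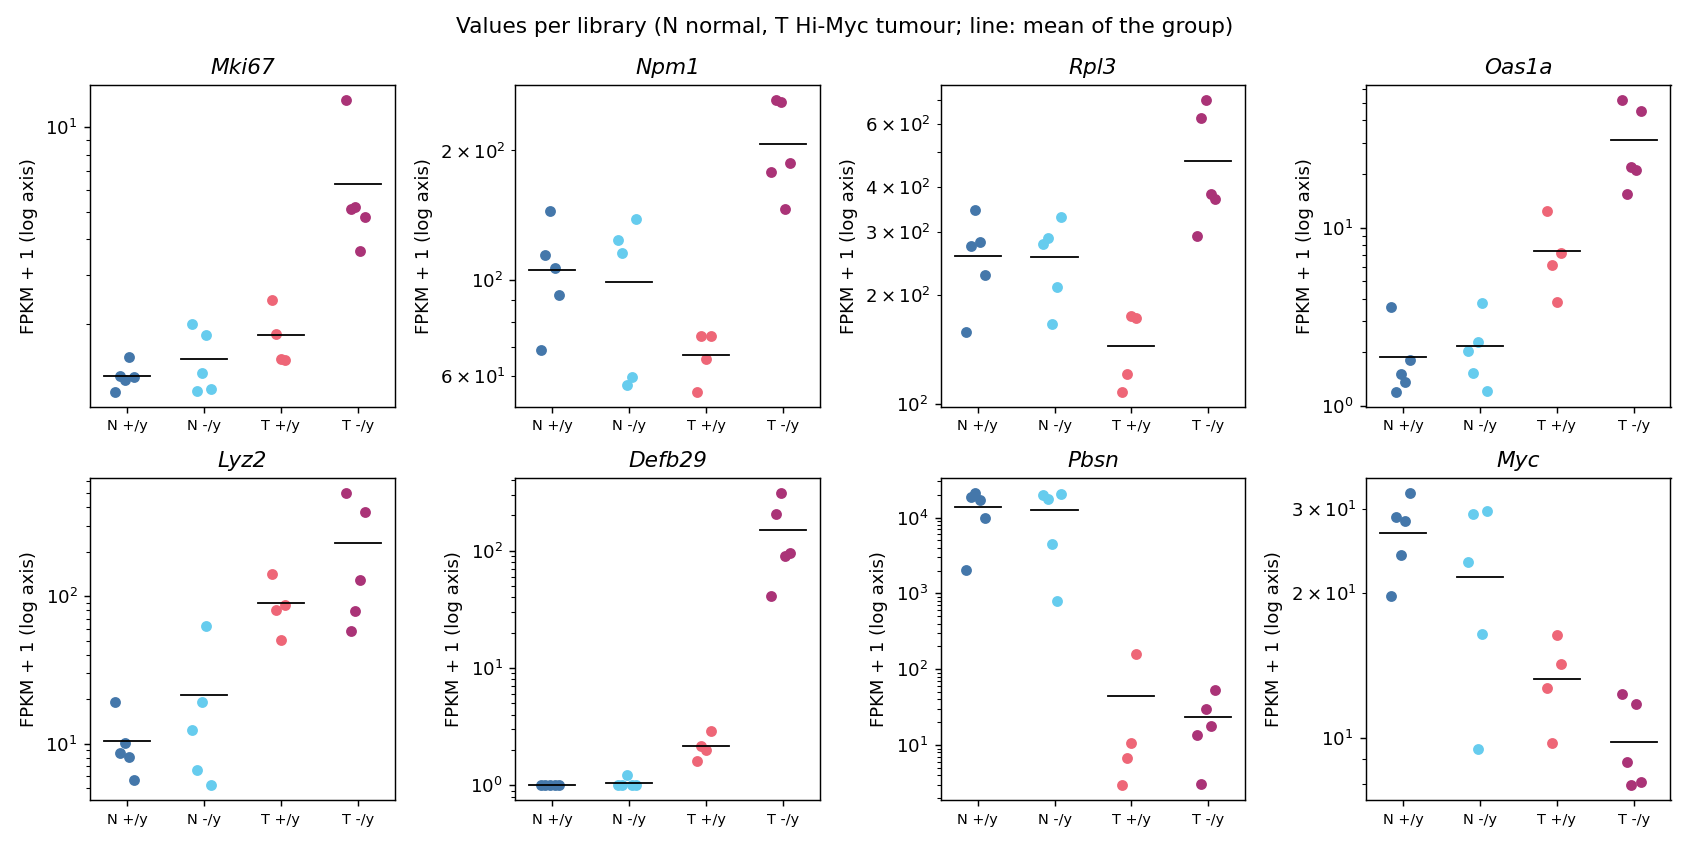
FPKM+1 on a log axis in each library for 8 genes (Mki67, Npm1, Rpl3, Oas1a, Lyz2, Defb29, Pbsn, Myc) by group, with the group mean as a line. Defb29 averaged 148 FPKM in Otud6a-/y tumours and 1.15 in Otud6a+/y tumours, and Pbsn was lower in both tumour groups.

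**Figure D4:**
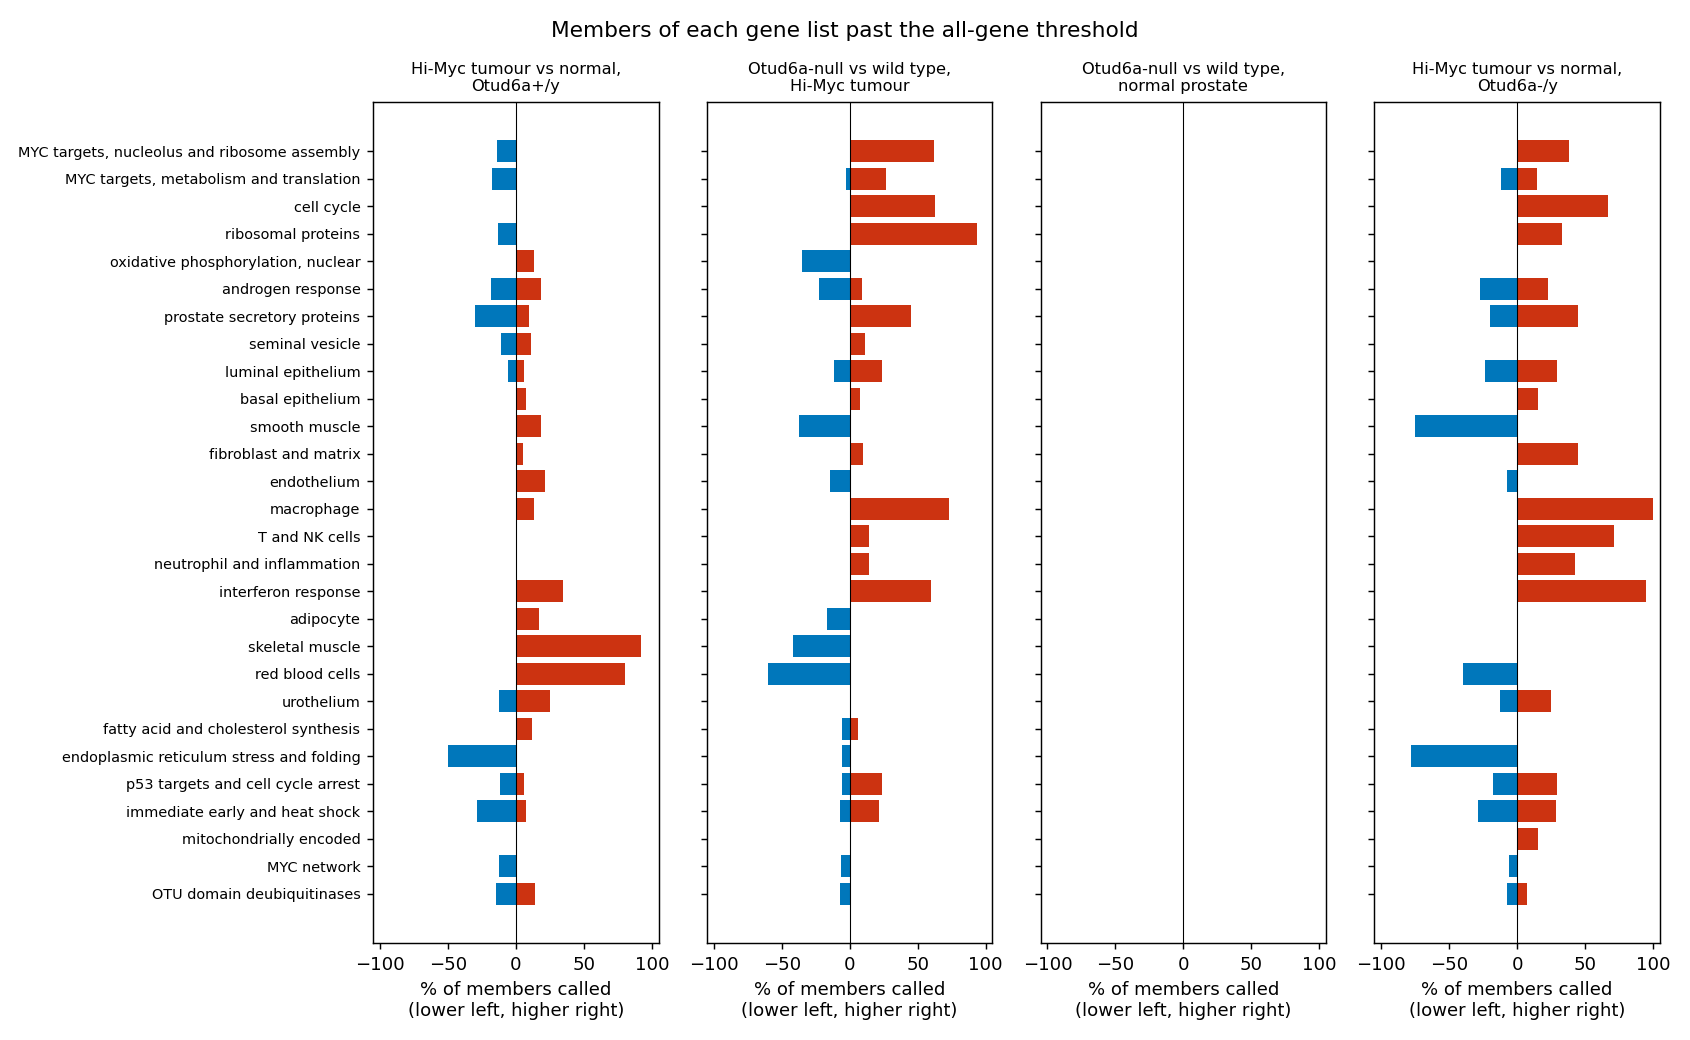
Percent of measured members of each gene list called higher or lower in 4 comparisons. The panel for normal prostate holds 0 calls, and ribosomal protein genes were higher in 28 of 30 cases in Otud6a-/y tumours.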

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

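The tests of tissue content, scaling and Myc in this part were chosen only after the results were seen, while the splits and the macrophage covariate were set before. Samples were compared within groups by Dixon's criterion, which by chance sets apart about 1 in 20 groups. It set apart 7 of 52 measures and 177 of 777 sets of values of named genes. In normal Otud6a+/y replicate 1 the seminal vesicle list (23.78% of reads) and the macrophage list (0.01438%) were the highest. Normal Otud6a-/y replicate 3 had the highest ratio of library size to reads (1.311), the most genes above 0 (24704) and the highest mitochondrial share (4.953%), and normal Otud6a-/y replicate 4 the highest seminal vesicle share (34.87%). In Otud6a-/y tumour replicate 4 the skeletal muscle list (0.09584%) was the highest.

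Named genes set apart numbered 45, 1, 2 and 9 in normal Otud6a+/y replicates 1, 3, 4 and 5, and 2, 28, 18 and 1 in normal Otud6a-/y replicates 1, 3, 4 and 5. They numbered 9, 5, 2 and 12 in Otud6a+/y tumour replicates 1, 2, 4 and 5, and 14, 5, 15 and 9 in Otud6a-/y tumour replicates 1, 3, 4 and 5. The named genes are not independent of each other, since many belong to the same tissues.

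The Hi-Myc change differed between genotypes by the interaction test in 1285 genes. The 8 smallest p-values gave log2 differences of 3.28 for AC130671.1, 5.75 for Defb29, 2.27 for Mpp1, 3.45 for Slc30a10, 5.03 for Havcr1, 2.87 for the unannotated feature on chromosome 9, 1.95 for Tmem156 and 2.86 for Tmem54. AC130671.1 and Defb29 are listed at 0 in all libraries of 1 normal group, so their fitted values depend on the pseudocount and are no bounds.

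Splits of the samples, the real one included in each count, were used to ask whether chance can give as many calls. For gene counts chance was unlikely in 4 comparisons, where 1 of 100 is the fewest that such a count can reach. As many genes came from 2 of 100 splits for the Hi-Myc change with Otud6a (real 2352, highest other 4002). It was 1 of 100 for loss of Otud6a in tumours (2944, 1553), 1 of 100 for the Hi-Myc change without Otud6a (3247, 1719) and 1 of 100 for the interaction (1285, 875). No allowance was made for testing several comparisons. The split with 4002 genes sets normal Otud6a+/y replicate 1 with the 4 tumours against the other normal libraries of that genotype, and so points to a structure of the samples in which that library stands apart from its group. In normal prostate 100 of 100 splits gave as many as the real 0 genes (highest other 35). For list counts chance cannot be excluded in any comparison: 32 of 100 splits (real 12, highest other 16), 26 (14, 17), 12 (13, 17), 35 (12, 16) and 33 (12, 17) in the order Hi-Myc with Otud6a, loss in tumours, loss in normal prostate, Hi-Myc without Otud6a and interaction.

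Cell cycle genes were higher in Otud6a-/y than in Otud6a+/y tumours (15 of 24). Macrophages as the whole cause are argued against, since 10 of 24 still passed with the macrophage score as a covariate. The median log2 was 0.96 before (median SE 0.26) and 0.71 after (median SE 0.29). That score holds macrophage genes only, so it cannot decide for other immune cells. The library size used for scaling is argued against too, since 16 passed after quantile normalization. Dilution of epithelium by tissue of another organ in the Otud6a+/y tumours could not be excluded: the cell cycle score minus the luminal score was -4.07 ± 0.659 in Otud6a-/y and -4.51 ± 0.650 in Otud6a+/y tumours (exact two-sided permutation p = 0.373 over 126 arrangements). A biological effect of Otud6a on proliferation may stand behind the difference, but these data leave it and the tissue content of the Otud6a+/y libraries open together.

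Skeletal muscle genes were higher in Otud6a+/y tumours than in normal prostate, and oxidative phosphorylation genes higher in them than in Otud6a-/y tumours. For the oxidative phosphorylation genes, skeletal muscle tissue in Otud6a+/y tumour replicates 1 and 2 is a candidate source: without them 0 of these genes were called lower in Otud6a-/y tumours, their median turning from -1.02 to 0.11, while limma still called 1849 genes. For the muscle genes the same step decides nothing, since the 2 libraries were chosen by that list. That 0 of its genes were then called against normal prostate follows from the choice. The other 2 Otud6a+/y tumours had 0.0152% and 0.0336% muscle reads, beside 0.0055% to 0.0244% in normal prostate with Otud6a. Whether the muscle came with the tissue taken or with a different organ stays open, since the same 2 libraries carried Prol1 and Pip.

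Mouse Myc was lower in Hi-Myc tumours than in normal prostate with Otud6a. Without the 4 libraries rich in seminal vesicle transcripts Myc still passed (adjusted p = 0.0153). This argues against seminal vesicle tissue as the cause in tumour replicates 1 and 2 only. Those are the muscle-rich tumours, so the step cannot decide for replicates 4 and 5 (15.41 and 13.24 FPKM). The 2 normal libraries rich in seminal vesicle transcripts had 18.78 and 15.47 FPKM. For skeletal muscle as the whole cause the evidence is mixed. Against it, the 2 tumours without muscle had at most 15.41 FPKM, below the lowest normal library with Otud6a (18.78), at an exact two-sided permutation p of 0.0476, the smallest that 21 arrangements allow. Both of these tumours were, however, rich in seminal vesicle transcripts (26.1% and 25.3% of reads). Otud6a-/y tumours, with at most 0.0958% muscle reads, fell by 1.05 as well. But without the 2 muscle-rich libraries the fold went from -1.01 (SE 0.28) to -0.78 (SE 0.36) and no longer passed (adjusted p = 0.202), with 2 tumours left. This test was read more than once after its result. The 2 tumours lay below every normal library with Otud6a, but not below all normal libraries (normal Otud6a-/y replicate 3 had 8.446 FPKM). Since both carried seminal vesicle transcripts instead, their low Myc cannot exclude muscle as the source in the other tumours. The question is left undecided. Repression of the mouse gene by the human transgene product is a possible explanation that was not tested. A part played by muscle or seminal vesicle tissue stays open. A lower share of prostate epithelium in all 4 tumours, in which Hoxb13 was at most 4.19 FPKM, was not tested either.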

How the results depend on the processing

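Alternatives that leave out libraries by tissue or mitochondrial content or by standing apart, scaling to the sum of reads, and voom were chosen only after the results were seen; the rest were planned. The cause of each change was not tested. Counts are genes called unless lists are named.

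No filter gave 1426 for Hi-Myc with Otud6a and 574 for the interaction. Only the 2 groups compared gave 1830 for loss of Otud6a in tumours, and a log2 fold change of at least 1 gave 1799 there and 1876 for Hi-Myc without Otud6a. With an estimated correlation 0 lists were called for Hi-Myc with Otud6a, 0 for loss in tumours, 0 for loss in normal prostate, 0 for Hi-Myc without Otud6a and 0 for the interaction. The block for replicate number changed no count by over 1.5 times (1792, 2612, 0, 2913 and 1017), and the Myc interaction (main -0.04) became 0.0877. Numbers do not pair the libraries: 27 same-number pairs had a median residual correlation of -0.0145 (-0.670 to 0.586), and 4 of 19 libraries fitted best with their own number.

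Without libraries rich in seminal vesicle transcripts, Hi-Myc with Otud6a gave 4381 and the interaction 2588, and normal prostate 8 lists; in normal prostate Pigr became 0.209, Spink1 0.08785 and the secretory list 0.07653, and the Myc interaction 0.2269. Without the 2 muscle-rich libraries Hi-Myc with Otud6a gave 18 (13 shared) and loss in tumours 1849 (1223 shared), and the oxidative phosphorylation list became -0.1861 in the first and 0.1066 in the second. Without the 3 libraries rich in mitochondrial reads they gave 681 and 1666, and the fibroblast list in tumours became -0.2085. Without the 3 normal libraries that stand apart Hi-Myc with Otud6a gave 4563 and normal prostate 3 lists; there Mcm5 became -0.1081, Cox6c -0.02309, Pigr 0.3249, Azgp1 0.1036, Smtn -0.007906, C1qa -0.05937, Cfd -0.2443 and Fabp4 -0.264, and the lists secretory 0.05181, endothelium -0.0008054, macrophage -0.08034, adipocyte -0.1705 and MYC network -0.02841 (main -0.1137, where only the direction of the list test turned). Scaled to the sum of reads, the Myc interaction became 0.2335.

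Leaving out 1 library gave 298 to 3859 for Hi-Myc with Otud6a, 1855 to 2860 for loss in tumours, 0 in normal prostate, 2264 to 3397 for Hi-Myc without Otud6a, 653 to 2101 for the interaction, and 7 to 15 lists in normal prostate. Fabp4 there ranged from -0.02848 to 1.456, and the Myc interaction from -0.3053 to 0.1082.

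Named genes refitted without each library in turn gave, over all these runs, 2361 with the same outcome, 254 weaker or ended, 23 stronger and 9 reversed. In single settings the weaker and the unchanged numbered 68 and 75 without muscle-rich libraries, 61 and 148 without mitochondria-rich ones, 39 and 216 with only 2 groups, 32 and 238 with no filter, 25 and 243 with voom, and 25 and 242 with the block. Voom called 1652, 2540, 0, 3109 and 957 genes. The 77 list results not called, refitted without each library in turn, gave 780 runs with the same outcome, 65 with a changed direction of the test and 39 newly called.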

Other observations

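All tests in this part were chosen only after the results were seen, except the list tests. Lists not described above gave the following counts of members higher and lower in Hi-Myc tumours with Otud6a against normal, then in Otud6a-/y against Otud6a+/y tumours: androgen response 4 and 4, then 2 and 5 of 22; luminal epithelium 1 and 1, then 4 and 2 of 17; basal epithelium 1 and 0, then 1 and 0 of 13; seminal vesicle 1 and 1, then 1 and 0 of 9 (median -5.10); urothelium 2 and 1, then 0 and 0 of 8; adipocyte 1 and 0, then 0 and 1 of 6; fatty acid and cholesterol synthesis 2 and 0, then 1 and 1 of 17. P53 targets gave 1 and 2, then 4 and 1 of 17, immediate early and heat shock genes 1 and 4, then 3 and 1 of 14, MYC network genes 0 and 2, then 0 and 1 of 16, and OTU domain deubiquitinases 2 and 2, then 0 and 1 of 14. None of these was called by the list test in those comparisons. Median and mean differed in sign for androgen response and OTU domain genes in the first comparison (0.39 and -0.24, 0.09 and -0.09), and for basal and immediate early genes in the second (-0.14 and 0.10, 0.13 and -0.12). In the Hi-Myc comparison without Otud6a they differed for immediate early (0.26 and -0.40), endothelial (0.03 and -0.07) and skeletal muscle genes (0.00 and -0.17), and in the interaction for MYC network genes (-0.03 and 0.15). The test of urothelium pointed up between tumours where median and mean were negative (-0.36 and -0.11). In normal prostate they differed for seminal vesicle genes (0.19 and -0.10) and metabolic MYC targets (-0.04 and 0.00).

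The unannotated feature beside Otud6a followed the genotype labels but for 1 read in Otud6a-/y tumour replicate 3, and Dgat2l6 but for normal Otud6a+/y replicate 4, which had 0 reads of it. That leaves little room for a swap between genotypes, but it says nothing of tissue or tumour content. Igbp1, 64.4 kb from Otud6a and between them, had 6902 reads in Otud6a+/y and 11971 in Otud6a-/y libraries, so a loss of the whole interval is not what was seen. Why reads of both are missing without Otud6a was not tested.

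Otud6a+/y tumours fell into pairs by tissue, replicates 1 and 2 with Prol1, 2310057J18Rik (5.95% and 3.63% of reads), Smr2, Dcpp1, Mup4 and Pip, and replicates 4 and 5 with Svs2. No Otud6a+/y tumour had Hoxb13 above 4.19 FPKM. The genotype comparison in tumours is therefore also a comparison of libraries with and without these tissues. Leaving out replicates 1 and 2 removes one of them and leaves the other, and no setting removes both, since no Otud6a+/y tumour would remain.

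Among prostate products the tumours without Otud6a held much Sbp (8.99%, 7.49%, 2.94%, 1.04% and 0.0305% of reads in replicates 2, 3, 4, 5 and 1) and Spink1 (15637 ± 16154 FPKM), while 9530053A07Rik took 15.7% to 22.6% of reads in 7 normal libraries. Normal Otud6a+/y replicate 1 also held much Sbp (3.20% of reads) and Spink1 (8650 FPKM), with 0.669% 9530053A07Rik. It differed from these tumours in other products. They had 0.000818% to 0.0724% 9530053A07Rik and at most 0.735% seminal vesicle reads, where it had 23.8%.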
